A study of Mus musculus with 6 samples.

How the data were processed

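Endothelial cells (EC) were sorted from normal mouse brain and from glioma that had grown in the brain for 3 weeks after injection of tumor cells, in C57BL/6 mice, per the labels. RNA was taken up in Trizol, and libraries were built from total RNA with a Lexogen QuantSeq kit, per the labels' protocols. QuantSeq reads come from the 3′ end of polyadenylated transcripts, so values need no correction for gene length. The 6 libraries form a normal group of 3 and a glioma group of 3, taken from the sample titles. Bowtie2, edgeR and the mouse build mm10 were named without role or version, per the submitters' processing notes. The tool that counted reads per gene, its use of strand, the gene annotation and the normalization step are not given in the sources used here.

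Each library came as a file of its own with 1 value for each of 24421 gene symbols. The deposited values are on a log2 scale. Their form was read from the values, since no header states it. The highest value was 20.85 in every library and belonged to Rn45s, a ribosomal RNA gene that held 11.1% to 11.3% of each library's sum. After back-transformation as 2 to the power of the value, minus 1, at least 99.97% of the non-zero values lay within a tolerance of 0.02 of a whole multiple of 1 divided by 6, as means over 6 libraries of whole numbers would. The deposited log2 values were therefore read as log2(x + 1) of values quantile-normalized across the 6 libraries by the authors, with genes without reads kept at 0. The summed back-transformed values were nearly equal in all libraries. This processing removes the library totals, so sequencing depth is unknown, and no interval that needs a count is given. It also gives each library a gap between 0 and its lowest non-zero value, which ranged from 0.22 in normal replicate 3 to 7.43 in normal replicate 1. A gene missed in normal replicate 1 therefore differs by at least 7.43 on the log2 scale from a gene just detected there. Genes that most cells use are among those at 0, so a 0 is reported only as a gene listed at 0, with the value of each library and no mean.

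The design fixed before the data were examined foresaw counts and a count model, and named limma for the case of normalized values. The files hold no counts, so limma was used. The deposited log2 values were fitted with limma 3.58.1 in R 4.3.3, with a mean trend in the variance prior, the group as the only term and 4 residual degrees of freedom. Genes with a back-transformed value of at least 1 in at least 3 libraries were tested, which left 11862. The p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A difference is glioma minus normal on the log2(x + 1) scale, where the gap between 0 and the lowest value of a library widens the difference of a gene listed at 0, and is given with its standard error (SE).

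Lists of 650 different symbols were fixed with the design, as 37 lists. Of the symbols, 619 stood in the files as written, 10 stood under another symbol of the same gene and 21 were not matched, among them all members of the list of mitochondrially encoded genes. The functional lists were blood-brain barrier transporters, tight and adherens junctions, Wnt/beta-catenin signalling, tip cell and sprouting angiogenesis, VEGF and angiopoietin-Tie ligands and receptors, caveolae and fenestrae, leukocyte adhesion and activation, basement membrane and extracellular matrix, integrins, cell cycle and proliferation, hypoxia and glycolysis, oxidative phosphorylation, interferon response, antigen presentation, Notch and arterial identity, venous identity, TGF-beta and BMP signalling, endothelial-to-mesenchymal transition, YAP/TAZ targets, fatty acid uptake and cholesterol synthesis. Lists for RNA quality held dissociation stress genes and mitochondrially encoded genes. Marker lists covered endothelium, pericytes and smooth muscle, fibroblasts, microglia and macrophages, T and NK cells, B cells, granulocytes, erythroid cells, platelets, neurons, astrocytes, the oligodendrocyte lineage, choroid plexus and ependyma, and glioma or neural progenitor cells. The 36 lists with tested members were tested with camera from limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over those lists. The camera test asks whether a list's members differ more than the other genes do. It was repeated with an estimated correlation, and fry was run as a self-contained test.

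Genes to name were also fixed by rule. The rule took the 8 largest rises and 8 largest falls among genes past the threshold, of which there were none, and 14 anchor genes whatever their result. It also took up to 2 members with the smallest p from each functional list without a called member, and the 3 highest members of each marker or quality list. The mean CPM of 20 that the rule asks for was replaced by the same share of the summed back-transformed values. A gene that the rule names is not reported here. Further genes are described as chosen after their values were seen. Gene positions are those of the GENCODE annotation of build GRCm38 (mm10). Gene symbols with the same value in every library as another symbol numbered 111, among them Hba-a1 and Hba-a2 or Pcdha family members, and such reads cannot be split between copies.

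The gene and list tests were tested on simulated data with the real genes' means and spread. With 50 changed genes per size and 11862 genes, the limma test recovered 0, 0, 5 and 12 genes at log2 changes of 1, 2, 4 and 6, and called 0 unchanged genes. At 0.25 times the real spread it recovered 13, 25, 36 and 50 and called 2 unchanged genes. The list test gave a list of 25 genes shifted by 1.5 on the log2 scale an adjusted p of 0.000237, and called 0 of 30 unshifted lists. Simulated genes varied independently, with no gap above 0, so this does not show how often lists of correlated genes are called falsely. The alternatives tried were other filters, pseudocounts and thresholds, the replicate number as a block, each library left out, both libraries numbered 1 left out, and lists without shared members. Added after the values were seen were a shared floor at 7.43, genes above 0 in all 6 libraries only, no trend in the variance prior, centring, array weights, averaging normal replicates 2 and 3, and leaving out normal replicate 1 with that floor or together with glioma replicate 3. Figures and tables were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.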

Results

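Endothelial cells from normal mouse brain were compared with endothelial cells from high-grade glioma, grown for 3 weeks from GL26l glioma cells injected into the brain of congenic mice. The comparison asks which genes differ between tumor vessels and brain vessels, as the series' design text puts it. Each group held 3 libraries, from RNA sets that the text calls independent. Nothing in the labels says that each set came from a different animal, so p-values measure the spread between these samples, which can be technical. Endothelial transcripts were abundant in all 6 libraries. The 26 tested members of the pan-endothelial list lay above 0 in each library. The highest of them was Egfl7, a secreted endothelial factor, at a log2 value of 17.52 ± 0.18 (SD, n = 3) in normal and 16.15 ± 0.81 (SD, n = 3) in glioma libraries. Pecam1 stood at 15.89 ± 0.55 and 15.42 ± 0.55 (SD, n = 3 each), and Cd34 at 15.63 ± 0.66 and 15.26 ± 0.45. The list did not pass the limma camera test (median difference -0.21, adjusted p = 0.439), and its median was 0.28 without glioma replicate 1.

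Detection was uneven. Genes above 0 numbered 7446 in normal replicate 1, 11853 in normal replicate 2 and 13072 in normal replicate 3, and 13108, 10954 and 10013 in glioma replicates 1, 2 and 3. Of 2391 genes above a log2 value of 9 in the other 5 libraries, 142 (5.94%) were listed at 0 in normal replicate 1. The same count was 26 of 2369 (1.10%) for glioma replicate 3 and at most 3 for each other library. Sequencing depth is unknown, since no read counts are in the files used here. Across the 5880 genes above 0 in all 6 libraries, Pearson's r was 0.97 between normal replicates 2 and 3, while the next highest pair, normal replicate 3 and glioma replicate 2, gave 0.82. Normal replicate 1 correlated at 0.58 and 0.60 with the other normal libraries and at 0.66, 0.67 and 0.56 with glioma replicates 1, 2 and 3. These are correlations across genes, which are not independent replicates. Normal replicates 2 and 3 shared 0.37% of values exactly, so they are not copies of the same file. Whether they differ by more than sampling noise cannot be tested without counts. Date-like numbers in the file names are shared by normal replicates 2 and 3, and by glioma replicates 2 and 3. No such number is shared across the groups, so batch and group cannot be told apart.

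**Figure D1:**
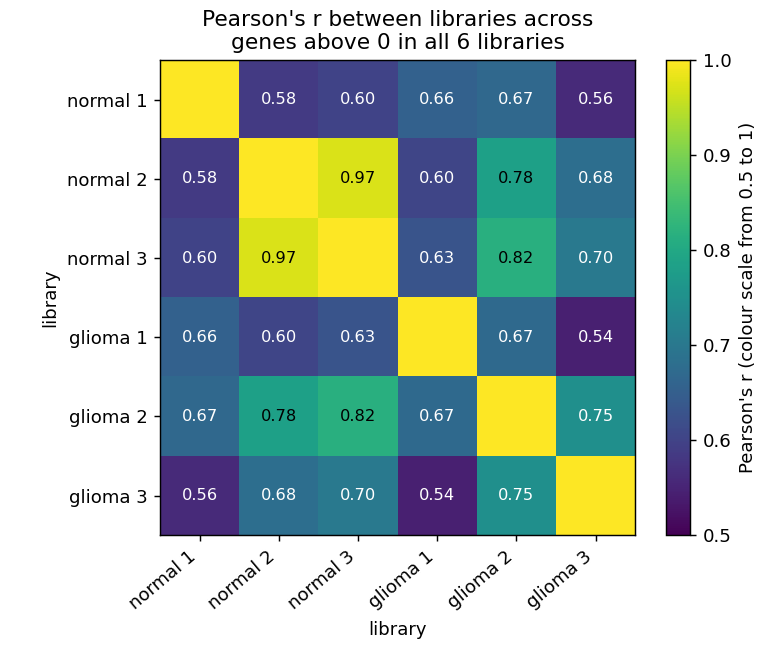
Pearson's r between each pair of the 6 libraries, across the 5880 genes above 0 in all of them, on a colour scale from 0.5 to 1. Normal replicates 2 and 3 stand apart as a pair at 0.97, and normal replicate 1 lies between 0.56 and 0.67 from every other library.

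At the preset correlation of camera, 7 of 36 lists passed, with proliferation, matrix, hypoxia, oxidative phosphorylation, sprouting and myeloid lists higher and the platelet list lower in the glioma libraries. The myeloid call was lost without glioma replicate 3 (adjusted p = 0.556), and the platelet direction turned upward with a shared floor (adjusted p = 0.976). With an estimated correlation 0 lists passed, where the smallest adjusted p was 0.490, and no single gene passed the test over all genes. Of 11862 genes tested with limma, 0 passed a Benjamini-Hochberg adjusted p of 0.05, and the smallest adjusted p was 0.875. An unadjusted p under 0.05 was reached by 509 genes, 279 higher and 230 lower in glioma, where 593.1 are expected by chance. The 3 glioma libraries lay wholly above the 3 normal libraries for 820 genes and wholly below for 756, together 13.3% of genes, where chance gives 10%. These are 1576 genes, while 3 other splits of the libraries into 3 and 3 gave 2281, 2116 and 1827. The remaining splits gave 462 to 1046, so the excess over 10% is not particular to the real groups. The median spread within groups was a log2 SD of 2.08 over all genes and 0.90 over genes above 0 in all 6 libraries. On simulated data with that spread, 12 of 50 genes changed by a log2 of 6 were recovered, and 0 of 50 changed by 2, so single-gene differences of these sizes were mostly not detectable. Leaving out normal replicate 1 gave 1211 genes at an unadjusted p under 0.05 and 0 past the adjusted threshold, with a smallest adjusted p of 0.142, while 303 and 316 genes reached that unadjusted p without normal replicates 2 and 3. The number of lists past the threshold was 2 without normal replicate 2 or normal replicate 3 and 11 without glioma replicate 1.

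Proliferation genes were above 0 for more list members in the glioma libraries than in the normal libraries. The cell cycle list rose in glioma (30 tested members, median 3.54, camera adjusted p = 1.12e-08, and adjusted p = 0.490 with an estimated correlation). Its glioma libraries lay above all normal libraries for 10 members and below for 0. Ccnb2, a mitotic cyclin, was listed at 0 in all 3 normal libraries and at 8.33, 4.78 and 8.51 in the glioma libraries. Bub1b, a spindle checkpoint kinase, was listed at 0 in the normal libraries and at 7.76, 8.52 and 5.22. Mki67, the gene of the proliferation marker Ki-67 (chromosome 7, 135689784 to 135716361), was at 0 in normal replicates 2 and 3, but at 9.57 in normal replicate 1 beside 11.74, 7.92 and 7.80 in glioma. The members above 0 numbered 19, 17 and 20 of 32 in the normal libraries and 32, 31 and 26 in the glioma libraries. Over the 9 members above 0 in all 6 libraries the median difference was 0.97, and it was also 0.97 with every value raised to the shared floor, so the size of 3.54 rests on genes listed at 0. The list passed the camera test without each library in turn, with adjusted p from 5.65e-14, without normal replicate 1, to 0.000721. Its median in normal replicate 1 was 8.97, above glioma replicates 2 and 3 (8.39 and 8.05). In normal replicates 2 and 3 the median was 5.13 and 4.04, so the rise rests mostly on that pair. Glioma replicate 1, with the highest cell cycle median (9.96), also had 11 of 12 fibroblast and 22 of 25 myeloid markers above 0. This library had the most genes above 0 (13108) and a lowest value above 0 of 0.415, so such counts can include very low values. Its myeloid median was 5.13, below normal replicate 1 (7.54) and glioma replicates 2 and 3 (6.42 and 9.47). Normal replicates 2 and 3 were lower (4.26 and 3.32). Which cells carried the cell cycle transcripts was not tested.

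Sprouting genes stood higher in normal replicate 1 than in the other normal libraries, with list medians of 10.61, 8.66 and 8.67 in normal replicates 1, 2 and 3. This was not particular to sprouting genes. The cell cycle (8.97, 5.13 and 4.04) and integrin medians (9.64, 7.10 and 7.75) differed likewise. Other lists went the other way, such as barrier transporters (11.36, 12.83 and 12.79). The tip cell list rose (25 tested members, median 0.47, camera adjusted p = 0.014, and adjusted p = 0.680 with an estimated correlation), with 5 members wholly higher and 0 wholly lower in glioma. Prnd, which encodes a prion-like protein and overlaps the readthrough gene Prn, was listed at 0 in the normal libraries and at 9.22, 7.60 and 9.91 in the glioma libraries. Prn had values of its own, at 0 in the normal libraries and at 8.18, 7.25 and 9.04 in glioma. How reads from the overlap were assigned is not known. Kcne3, a potassium channel subunit, was at 8.50 in normal replicate 1, at 0 in normal replicates 2 and 3, and at 10.74, 10.88 and 10.65 in glioma. Apln, which encodes the peptide ligand apelin (X chromosome, 48025146 to 48034853), differed by 3.66 (SE 1.77, limma adjusted p = 0.875), with 13.82 in normal replicate 1, 6.21 and 6.52 in normal replicates 2 and 3, and 12.50 ± 0.70 (SD, n = 3) in glioma. Angpt2, an antagonistic ligand of the Tie2 receptor (chromosome 8, 18690263 to 18741562), likewise stood at 13.15 in normal replicate 1, at 8.70 and 8.67 in normal replicates 2 and 3, and at 11.56 ± 0.58 in glioma. Without normal replicate 1 the differences were 6.14 for Apln and 2.88 for Angpt2, neither past the threshold. Esm1 was at 8.39 ± 0.78 and 8.86 ± 1.31. The list was not past the threshold without normal replicate 2 (adjusted p = 0.133), normal replicate 3 (0.196) or glioma replicate 2 (0.197), and leaving out each library in turn gave adjusted p from 1.59e-06 to 0.197. Its median was 1.09 without normal replicate 1, 1.32, 0.26 and 0.76 without glioma replicates 1, 2 and 3, and 0.24 over the 19 members above 0 in all 6 libraries.

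The VEGF and angiopoietin-Tie list did not pass (15 tested members, median -0.24, camera adjusted p = 0.898), and its median was 0.15 without glioma replicate 3 and 0.02 over the 10 members above 0 in all 6 libraries. Kdr, the main VEGF receptor of endothelium, was at 13.53 ± 0.28 and 13.29 ± 0.69 (SD, n = 3 each). Tek, which encodes Tie2, was at 12.72 ± 0.21 and 13.34 ± 0.56. Neither passed the limma test over all genes.

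**Figure D2:**
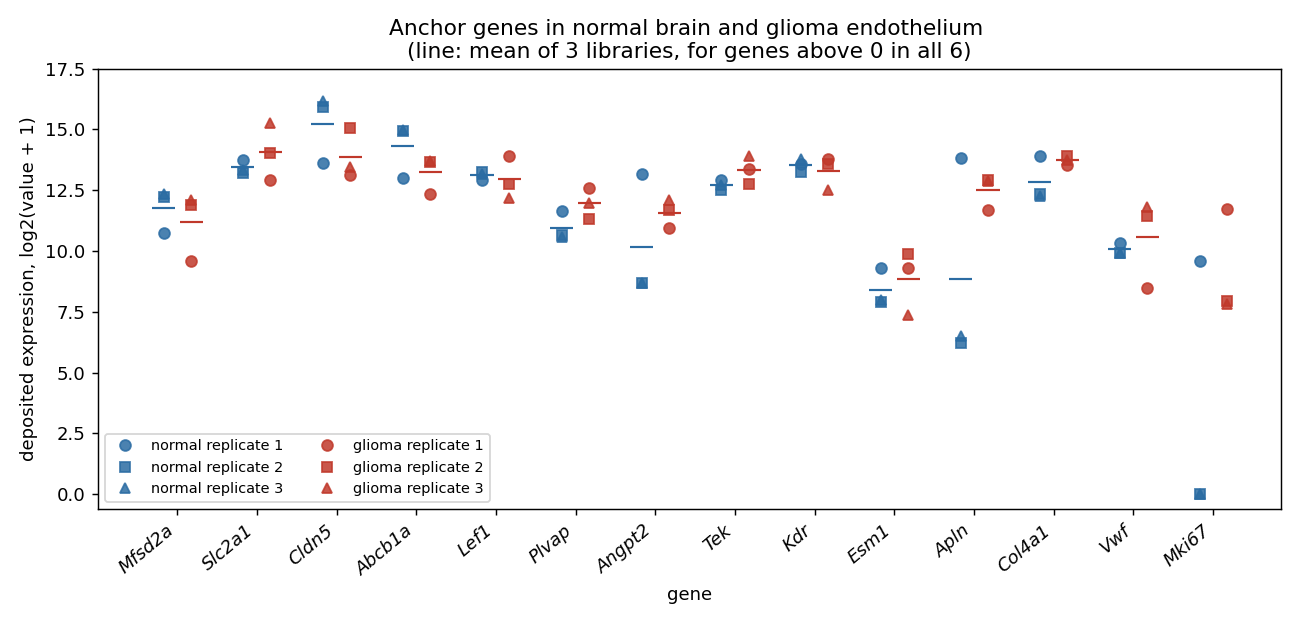
Deposited log2(value + 1) of the 14 anchor genes in each library, with normal libraries in blue, glioma libraries in red, a symbol per replicate number, and lines at group means for genes above 0 in all 6 libraries. Apln and Angpt2 of normal replicate 1 (13.82 and 13.15) lie above every glioma library, and Mki67 (9.57) lies within the glioma range. All of these lie above normal replicates 2 and 3. Cldn5 and Abcb1a of normal replicate 1 (13.62 and 13.00) also lie within the glioma range and below normal replicates 2 and 3. Kdr of normal replicate 1 (13.58) lies between normal replicates 2 and 3.

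The matrix list was higher in the glioma libraries, of which glioma replicate 1 had 11 of 12 fibroblast markers above 0, against at most 5 in any other library, and in glioma replicate 3 most microglia and macrophage markers were at their highest. The basement membrane list rose (28 tested members, median 0.91, camera adjusted p = 0.00218, and adjusted p = 0.490 with an estimated correlation), with 5 members wholly higher and 0 wholly lower. Col18a1, which encodes the basement membrane collagen that yields endostatin (chromosome 10, 77052178 to 77166548), rose from 9.16 ± 0.86 to 11.86 ± 0.16 (SD, n = 3 each) when adjusted over the list alone, a difference of 2.70 (SE 0.57). It was the only member of any of the 36 lists to pass adjusted over the list alone, and its limma adjusted p over all genes was 0.875. Timp1, a metalloproteinase inhibitor, was listed at 0 in the normal libraries and at 7.26, 5.97 and 11.30 in the glioma libraries. Col4a1, a chain of type IV collagen, was at 12.83 ± 0.93 and 13.72 ± 0.19, and Vwf at 10.06 ± 0.25 and 10.57 ± 1.83. Without normal replicate 2 or normal replicate 3 the list's adjusted p was 0.0711 or 0.0519, in a range from 1.59e-06 to 0.0711 over each library left out. Its median was 0.51 over the 21 members above 0 in all 6 libraries and 0.64 with the shared floor. The integrin list did not pass (10 tested members, median 0.40, adjusted p = 0.406), and its median was -0.11 without normal replicate 3. Itgb5 was at 0, 5.27 and 6.78 in normal and 7.79, 9.32 and 10.45 in glioma libraries, and Itga5 at 0, 4.71 and 3.37 against 5.60, 7.27 and 6.69.

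Metabolic lists also stood higher in the glioma libraries. The hypoxia and glycolysis list rose (26 tested members, median 0.86, 5 wholly higher, camera adjusted p = 0.00228, and adjusted p = 0.680 with an estimated correlation). Hk2, a hexokinase, was listed at 0 in the normal libraries and at 7.22, 6.05 and 10.06 in glioma. Pfkp, a phosphofructokinase, was at 0, 8.52 and 8.81 in normal and 10.43, 9.93 and 10.93 in glioma libraries. Slc2a1, the glucose transporter GLUT1 that also belongs to the barrier transporters, was at 13.43 ± 0.28 and 14.08 ± 1.16 (SD, n = 3 each). Without glioma replicate 3, where 18 of 24 measured microglia and macrophage markers were highest, the adjusted p was 0.0855, the highest in a range from 0.000128 over each library left out. The hypoxia list's median was 0.37 without normal replicate 1 and 0.50 over the 17 members above 0 in all 6 libraries. The oxidative phosphorylation list rose (29 tested members, median 0.73, 4 wholly higher and 1 wholly lower, camera adjusted p = 0.0437, and adjusted p = 0.490 with an estimated correlation). Ndufv1 of complex I was at 8.48 ± 0.58 and 9.81 ± 0.16, and Atp5a1 of ATP synthase at 11.42 ± 0.49 and 12.46 ± 0.61. Without normal replicate 2, normal replicate 3 or glioma replicate 3 this list was not past the threshold (adjusted p = 0.228, 0.268 and 0.191), and the lowest value with a library left out was 0.00209. Its median was 0.37 without glioma replicate 3.

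Barrier gene lists did not pass the test over all libraries. The blood-brain barrier transporter list had a median difference of -0.53 over 24 tested members (camera adjusted p = 0.132), with 2 members wholly lower and 0 wholly higher. It was past the threshold without normal replicate 1 (adjusted p = 0.0234, median -0.82) and without glioma replicate 3 (adjusted p = 0.00136), and the highest value with a library left out was 0.715, without glioma replicate 1, where the median was 0.15. Insr, the insulin receptor, was at 12.43 ± 0.11 and 11.06 ± 0.46 (SD, n = 3 each), and the amino acid transporter Slc38a5 at 11.69 ± 0.28 and 10.72 ± 0.31. Mfsd2a, a lipid transporter that limits transcytosis at the barrier (chromosome 4, 122946850 to 122961188), was at 11.76 ± 0.90 and 11.18 ± 1.40. Abcb1a, the drug efflux pump P-glycoprotein, was at 14.30 ± 1.13 and 13.24 ± 0.77. The junction list did not pass (18 tested members, median -0.04, mean 0.10, direction down, adjusted p = 0.975), with medians of -0.59, 0.02 and 0.06 without normal replicates 1, 2 and 3 and of 0.37 and 0.08 without glioma replicates 1 and 3. Cldn5, the main claudin of brain endothelium (chromosome 16, 18776847 to 18778262), was at 15.23 ± 1.40 and 13.88 ± 1.02, a difference of -1.35 (SE 0.82, limma adjusted p = 0.875), and Ctnna1 at 10.83 ± 0.35 and 12.04 ± 1.05. Without normal replicate 1 the differences were -2.16 for Cldn5, -1.71 for Abcb1a and -1.09 for Mfsd2a, none past the threshold. The Wnt list, of the pathway that maintains the barrier, did not pass (21 tested members, median -0.22, adjusted p = 0.143), though it did without glioma replicate 2 (adjusted p = 0.028, in a range up to 0.895 over each library left out). The median of the Wnt list was -0.98 without normal replicate 1 and 0.34 without glioma replicate 1. Lef1 was at 13.11 ± 0.16 and 12.95 ± 0.87, Lrp6 at 8.82 ± 0.68 and 6.87 ± 0.29, and Tcf7 at 8.36, 7.26 and 6.50 in normal against 1.81, 0 and 7.51 in glioma libraries.

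The caveolae and fenestrae list did not pass (12 tested members, 3 wholly lower, median -0.51, camera adjusted p = 0.135), and did without glioma replicate 3 (adjusted p = 0.0406, in a range up to 0.895 over each library left out). Its median was 0.11 without glioma replicate 1. Ptrf, which encodes cavin 1 of caveolae, was at 15.16 ± 0.24 and 13.78 ± 0.32 (SD, n = 3 each). Pacsin3 was at 9.97, 10.54 and 10.11 in normal and 8.38, 8.57 and 0 in glioma libraries. Plvap, the diaphragm protein of fenestrated endothelium, was at 10.96 ± 0.61 and 11.97 ± 0.64, in the opposite direction to the list and short of the threshold.

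Vascular inflammation lists did not pass over all libraries. The leukocyte adhesion list had a median of -0.14 and a mean of 0.03 (13 tested members, direction down, camera adjusted p = 0.715), and a median of 0.31 without glioma replicate 1. Cxcl12, a chemokine, was at 15.27 ± 1.72 and 13.44 ± 0.82 (SD, n = 3 each). Ackr1, a chemokine receptor of venules, was at 10.56 in normal replicate 1, 2.84 and 3.59 in normal replicates 2 and 3, and 6.65, 10.87 and 10.69 in glioma. The interferon list had a median of 0.27 (31 tested members, adjusted p = 0.503) and passed without glioma replicate 1 (adjusted p = 1.64e-06, in a range up to 0.934 over each library left out). The interferon list's median was -0.19 without normal replicate 1, -0.41 and -0.25 without glioma replicates 2 and 3, and -0.03 over the 19 members above 0 in all 6 libraries. Stat2 was at 0, 7.59 and 8.47 in normal and 9.38, 10.73 and 9.48 in glioma libraries, and Cxcl9 at 10.60, 0 and 0 against 6.70, 12.37 and 12.05. The antigen presentation list had a median of 0.25 (19 tested members, adjusted p = 0.135). It passed without normal replicate 1 (adjusted p = 0.0298) and without glioma replicate 1 (0.000256), in a range up to 0.863. The antigen presentation list's median ran from 0.05 to 1.40 with 1 library left out, and was -0.18 over the 12 members above 0 in all 6 libraries. Its class II members H2-Aa and H2-Ab1, which macrophages also express, were at 0, 0 and 0.58 and at 0 in all normal libraries, against 5.38, 9.20 and 12.18 and 4.81, 8.70 and 11.63 in glioma.

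Lists of vessel identity and signalling did not pass. The Notch and arterial list had a median of 0.21 but a mean of -0.05 and the direction down (18 tested members, camera adjusted p = 0.898), with medians of -0.04 and -0.03 without normal replicates 2 and 3. Alpl was at 11.44, 13.53 and 13.75 in normal and 0, 10.95 and 9.69 in glioma libraries, and Bmx at 8.83 ± 0.66 and 7.08 ± 0.43 (SD, n = 3 each). The venous list had a median of 0.49 (12 tested members, adjusted p = 0.898), with Ackr1 and Slc38a5 as its members of smallest p, and a median of -0.42 without normal replicate 1. TGF-beta and BMP genes had a median of 0.08 (21 tested members, adjusted p = 0.898), which was -0.41 and -0.05 without normal replicates 1 and 3 and -0.39 over the 12 members above 0 in all 6 libraries. Tgfbi was at 8.68, 0 and 2.17 in normal and 8.04, 7 and 11.05 in glioma libraries. The endothelial-to-mesenchymal list had a median of 1.18 (13 tested members, adjusted p = 0.135) and passed without glioma replicate 3 (adjusted p = 0.00783, in a range up to 0.39 over each library left out), but its median was 0.05 over the 7 members above 0 in all 6 libraries. Vim, which encodes vimentin, was at 11.49 ± 0.94 and 13.32 ± 1.25, and Snai1 at 0, 0 and 3.30 against 7.90, 5.71 and 6.77. YAP/TAZ targets had a median of -0.26 but a mean of 0.38 and the direction up (14 tested members, adjusted p = 0.961) and medians of 0.04 and 0.07 without normal replicate 1 and glioma replicate 1, with Tead1 at 9.08 ± 0.50 and 11.08 ± 0.54 and Amotl1 at 12.02 ± 0.36 and 10.97 ± 0.54.

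Lipid lists did not pass either. The fatty acid uptake list had a median of 0.43 (14 tested members, camera adjusted p = 0.898), with Fabp5 at 0, 7.20 and 6.99 in normal and 10.98, 5.77 and 10.58 in glioma libraries and Slc27a4 at 8.76 ± 0.13 and 7.64 ± 0.98 (SD, n = 3 each). The fatty acid median was -0.07 without glioma replicate 3 and -0.82 over the 6 members above 0 in all 6 libraries. The cholesterol list had a median of -0.11 but a mean of 0.71 and the direction up (18 tested members, adjusted p = 0.898), with medians of 0.00, 0.17 and 0.18 without normal replicate 2 and glioma replicates 2 and 3. Dhcr7 was at 0, 0 and 2.54 against 7.07, 7.08 and 7.78, and Insig1 at 0, 8.14 and 7.92 against 10.46, 8.62 and 8.02. Dissociation stress genes had a median of 0.41 (22 tested members, adjusted p = 0.135). That list was past the threshold without glioma replicate 1 (0.016) or glioma replicate 2 (0.0204), in a range up to 0.935, and its median ran from 0.05 to 0.66. Its highest members were close in both groups, with Junb at 13.89 ± 0.59 and 13.98 ± 1.02, Klf2 at 13.86 ± 0.12 and 13.76 ± 0.75, and Jund at 13.43 ± 0.71 and 13.98 ± 0.39. Of the list of mitochondrially encoded genes 0 symbols were matched, and it was not analysed here.

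**Figure D3:**
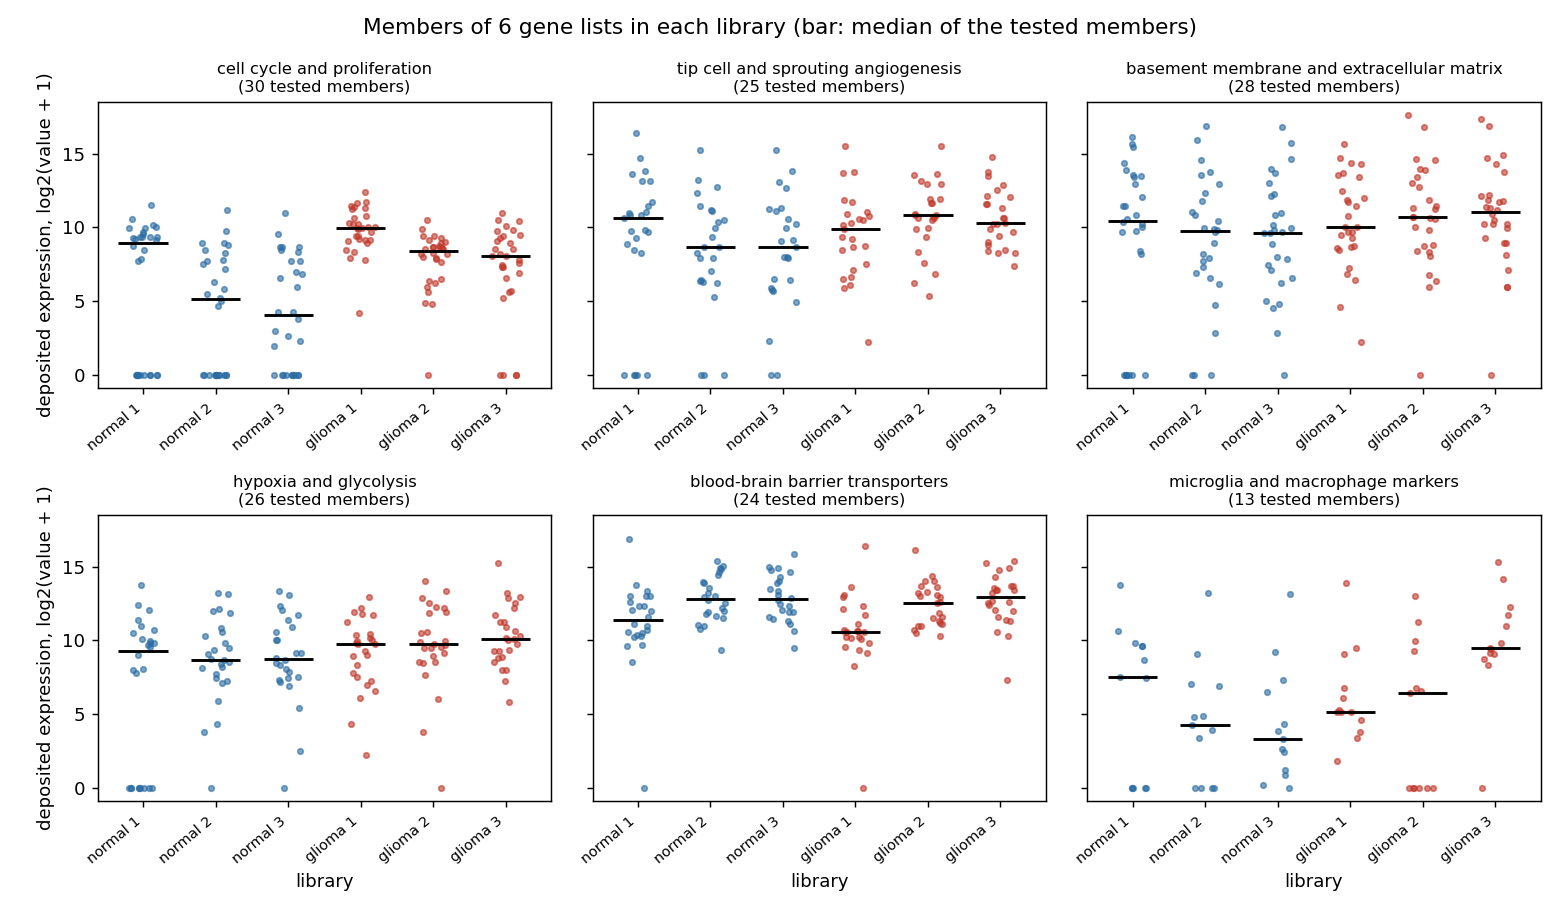
Deposited log2(value + 1) of the tested members of 6 gene lists in each library, 1 point per gene, with a bar at the median over members. The cell cycle medians are 5.13 and 4.04 in normal replicates 2 and 3 and 8.97 in normal replicate 1, beside 9.96, 8.39 and 8.05 in glioma, and the microglia and macrophage median is highest in glioma replicate 3, at 9.47.

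Among single genes above 0 in all 6 libraries with groups that do not overlap, those with the smallest p were named after their values were seen. The highest in glioma was Azin1, an inhibitor of antizyme that raises polyamine levels (chromosome 15, 38487427 to 38519266), at 9.83 ± 0.70 in normal and 12.70 ± 0.40 (SD, n = 3 each) in glioma, a difference of 2.87 (SE 0.52, limma adjusted p = 0.875). Trip10, Fyn, S100a11 and Zyx, of which zyxin is an adhesion and actin protein and Fyn a Src family kinase, differed by 2.29, 2.36, 2.38 and 2.61. Tcp1, Cldnd1, Cox7a2, Hmga1, Scamp3 and Rps21 differed by 1.87 to 2.61. On the lower side Flt3l, the ligand of the receptor Flt3 (chromosome 7, 45129788 to 45136432), was at 10.85 ± 0.30 and 6.67 ± 1.52, a difference of -4.18 (SE 0.94, limma adjusted p = 0.875). Arhgef15 was at 11.18 ± 0.12 and 9.14 ± 0.44. Zbed6, H2-Q4, Nek9 and Trim12c differed by -2.93, -3.27, -1.79 and -2.49. Genes listed at 0 in 1 whole group and above 0 throughout the other numbered 109, where other splits of the 6 libraries gave 28 to 614. Of these 109, 61 genes were listed at 0 in all normal libraries and above 0 in all glioma libraries, and 48 genes the other way round. The former included Clspn, a replication checkpoint factor, at 8.15, 8.61 and 8.32 in glioma, Irf8 at 6.75, 9.97 and 11.14, and Npr3 at 9.89, 6.52 and 9.53. The latter included the phospholipid transporter Abcb4 at 8.82, 7.20 and 6.40 in normal libraries, Atg10 at 8.81, 8.87 and 8.32, and Ggt1 at 8.49, 7.89 and 7.18.

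Markers of other cell types differed most between single libraries. The microglia and macrophage list rose (13 tested members, median 1.22, 2 wholly higher, camera adjusted p = 0.0261, and adjusted p = 0.845 with an estimated correlation). Its median was highest in glioma replicate 3, at 9.47, and without that library the adjusted p was 0.556, the highest in a range from 0.00109. Without normal replicate 2 or 3 it was 0.203 or 0.268. The median difference was 1.83 without normal replicate 1, and 2.19, 2.28 and 0.84 without glioma replicates 1, 2 and 3. Ctss, a lysosomal protease of myeloid cells, was at 14.15 in glioma replicate 3, 3.37 and 6.57 in glioma replicates 1 and 2, and 0, 4.26 and 4.36 in the normal libraries. Apoe was at 13.38 ± 0.34 and 14.06 ± 1.17 (SD, n = 3 each), and Ly6c2 at 9.60, 9.09 and 9.25 in normal and 9.50, 11.23 and 12.29 in glioma libraries. The platelet list fell by a median of 2.82 on 5 tested members (camera adjusted p = 0.0428, and adjusted p = 0.680 with an estimated correlation). With every value raised to the shared floor its direction turned upward (median 0.19, adjusted p = 0.976). With 1 library left out it passed only without glioma replicate 1 (adjusted p = 0.00831). It was at 0.0894, 0.0789 and 0.07 without normal replicates 1, 2 and 3, and at 0.116 and 0.556 without glioma replicates 2 and 3. The median was -4.91 without normal replicate 1, -4.32 without glioma replicate 1 and -0.82 without glioma replicate 3. Gp1bb was at 9.76, 6.92 and 7.18 in normal and 11.35, 8.38 and 0 in glioma libraries, Itga2b at 9.22, 7.83 and 7.07 against 8.22, 7.44 and 0, and Pf4 was above 0 in both libraries numbered 1 alone, at 8.96 and 9.06. Granulocyte transcripts were seen mainly in glioma replicate 1, with S100a9 at 12.84 and Ngp at 9.52 there and 0 elsewhere, and S100a8 at 10.25 there, 5.27 and 3.42 in normal replicates 2 and 3 and 0 elsewhere (3 tested members, median 0.52, adjusted p = 0.898). The granulocyte median was -0.93 without normal replicate 1 and -2.83 without glioma replicate 1.

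Pericyte and smooth muscle genes had a median of -0.40 (16 tested members, camera adjusted p = 0.255), with Rgs5 at 11.36 ± 1.97 and 11.56 ± 1.33, Abcc9 at 9.86 ± 0.87 and 11.55 ± 1.39, and Acta2 at 10.45 ± 0.14 and 10.43 ± 2.05 (SD, n = 3 each). The pericyte and smooth muscle median was -1.39 without glioma replicate 3 and -0.11 without glioma replicate 1. Fibroblast genes had a median of 1.95 (6 tested members, adjusted p = 0.218) and passed without glioma replicate 3 (adjusted p = 0.00783, in a range up to 0.895 over each library left out). The fibroblast list's median was 3.37 without glioma replicate 3 and 0.71 without glioma replicate 1. Of its 12 members 11 were above 0 in glioma replicate 1 and at most 5 in any other library. Col1a2 was at 7.43, 6.27 and 5.57 in normal and 10.93, 8.16 and 0 in glioma libraries, Col3a1 at 0, 3.42 and 2.12 against 9.76, 7.65 and 0, and Postn at 10.95 in normal replicate 1 and 9.64 in glioma replicate 1 alone. Erythroid genes had a median of 1.15 (6 tested members, adjusted p = 0.227) and passed without glioma replicate 3 (adjusted p = 0.00683, in a range up to 0.895). The erythroid median was 0.28 without normal replicate 1 and -0.08 without glioma replicate 1. The globin genes Hba-a1 and Hba-a2, which share all values, were at 13.69 ± 0.84 and 14.85 ± 2.70, and Hbb-bt at 11.45 ± 2.18 and 12.61 ± 3.16. T and NK cell genes (2 tested members, median -1.29, adjusted p = 0.715) and B cell genes (1 tested member, median 0.14, and -0.43 without normal replicate 1, adjusted p = 0.898) were sparse. The T and NK cell median was -0.18 without glioma replicate 1 and -2.09 without glioma replicate 2. Lck was at 8.63 and 8.62 in glioma replicates 1 and 2 and 0 elsewhere. Cd3d was at 7.67, 4.88 and 3.25 in normal libraries and 3.82 in glioma replicate 2, and Cd8b1 at most at 5.60. Ebf1, which pericytes also express, was at 13.15 ± 0.99 and 13.29 ± 0.16, while Cd22 and Pax5 reached at most 2.84 and 0.41.

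Brain cell lists did not pass over all libraries. Neuron genes had a median of -0.20 (14 tested members, camera adjusted p = 0.715), and passed as lower without glioma replicate 1 (adjusted p = 0.00313, in a range up to 0.99). The neuron median was 0.92 and 0.09 without normal replicates 2 and 3 and 1.11 and 0.98 without glioma replicates 2 and 3. Members above 0 numbered 16, 16 and 15 of 16 in normal replicates 2 and 3 and glioma replicate 1, and 4, 5 and 4 in normal replicate 1 and glioma replicates 2 and 3. Tubb3 was at 0, 6.76 and 6.14 in normal and 11.98, 5.53 and 0 in glioma libraries, Meg3 at 8.76 ± 0.79 and 9.75 ± 2.77, and Stmn2 at 8.36 ± 0.33 and 7.26 ± 3.43 (SD, n = 3 each). Astrocyte genes had a median of -0.18, and of -1.58 without normal replicate 1 (12 tested members, adjusted p = 0.433), with Sparcl1 at 14.86 ± 0.49 and 14.72 ± 0.16, Cpe at 12.91 ± 1.12 and 13.13 ± 0.14, and Slc1a2 at 12.47 ± 0.68 and 12.30 ± 1.77. Oligodendrocyte genes had a median of 0.77 (8 tested members, adjusted p = 0.849), which was -1.23 without normal replicate 1 and -0.20 with the shared floor. Mbp, a myelin protein gene, was at 0, 10.96 and 10.94 in normal and 3.12, 3.82 and 0 in glioma libraries, Cspg5 at 0, 9.77 and 9.11 against 10.49, 4.38 and 10.14, and Mal, which is also expressed outside this lineage, at 11.77 ± 2.56 and 10.65 ± 3.20. Choroid plexus and ependymal genes had a median of 1.49, and of -1.68 without normal replicate 1 (4 tested members, adjusted p = 0.406), with Enpp2 at 0, 10.65 and 11.34 against 5.89, 11.96 and 12.37, Ttr at 0, 8.32 and 7.79 against 5.25, 0 and 11.58, and Rarres2 at 0, 0 and 2.91 against 8.75, 5.06 and 6.43. Glioma and neural progenitor genes had a median of 1.83, and of -0.36 over the 3 members above 0 in all 6 libraries (9 tested members, adjusted p = 0.371), with Prom1 at 14.88 ± 1.22 and 14.32 ± 0.64, Vim as above and Nes at 10.43 ± 0.28 and 10.06 ± 0.46.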

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

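The settings named here as a shared floor, genes above 0 in all 6 libraries, no trend in the variance prior, array weights, centring, averaging of normal replicates 2 and 3, and pairs of changes were chosen after the results were seen. Across all alternatives 965 values were scored the same, 61 weaker, 35 stronger and 1 reversed. A list or anchor gene was scored the same if it stayed on its side of the threshold, even where an uncalled direction turned. A count of genes or lists was scored weaker or stronger if it changed by more than a set factor. The limma test called 0 genes at a Benjamini-Hochberg adjusted p under 0.05 with all filters, with the other pseudocount and without each library in turn, with 303 to 1211 genes at an unadjusted p under 0.05 when 1 library was left out. It called 15 genes without the trend in the variance prior (10 higher and 5 lower in glioma, all 15 at least 2-fold), of which 13 were listed at 0 in 1 whole group, and 6 genes with array weights (6 higher, all 6 at least 2-fold), where the weights ran from 0.122 for normal replicate 1 to 7.60 for normal replicate 3. Both settings change how much the spread of each gene or library counts, and the cause was not tested further. Camera put 7 lists past the threshold, and 4 with the stricter filter, 4 with a shared floor, 11 without both libraries numbered 1, 2 with normal replicates 2 and 3 averaged, 0 with an estimated correlation and 0 with fry, and from 2 to 11 with 1 library left out. The version of fry that asks for change in either direction put 4 lists past the threshold, tip cell and basement membrane at an adjusted p of 0.00131 and cell cycle and glioma or neural progenitor markers at 0.00163. By construction fry does not compare a list with other genes, and for the other settings the cause was not tested. With camera at its preset correlation, the cell cycle list stayed past the threshold under 19 of 19 other settings, the hypoxia list under 17, the basement membrane list under 16, the oxidative phosphorylation list under 13, the tip cell list under 12, the microglia and macrophage list under 12 and the platelet list under 6 of 18. The platelet markers turned upward with the shared floor (adjusted p = 0.976, in a range from 0.00831 to 0.556 with 1 library left out), where members listed at 0 no longer differ from members just detected in normal replicate 1. With the replicate block the limma test called 0 genes, with 610 at an unadjusted p under 0.05, and camera put 7 lists past the threshold, with platelet markers at an adjusted p of 0.0593 and blood-brain barrier transporters at 0.0217. Correlations of deviations between libraries of the same number were 0.13, 0.03 and 0.06 over all genes tested. Over genes above 0 in all 6 libraries they were 0.19, 0.15 and 0.06. Normal replicate 1 correlated best with glioma replicate 1 in both sets. Normal replicate 3 correlated best with glioma replicate 2 (0.09 and 0.19), so the numbers were not taken as pairs. Not run, because they need counts, were another size factor method, upper-quartile scaling, a negative binomial test, voom weights and leaving mitochondrial and erythroid genes out of library totals. Depth is unknown, so a gene listed at 0 in normal replicate 1, where the lowest value above 0 was 7.43, is not shown to be absent there.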

Other observations

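The tests of a glioma-like identity of normal replicate 1, of a difference tied to date-like numbers in the file names and of myeloid cells in glioma replicate 3, as well as array weights and the genes named in the next paragraph, were chosen after the results were seen. The tests of quantile normalization and of deeper detection, and the other splits of the libraries, were set before their results were seen.

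Some genes, picked for this pattern, stood high in normal replicate 1 and in all glioma libraries, and low in normal replicates 2 and 3. Igfbp4, which encodes a binding protein of insulin-like growth factors, was at 12.43 in normal replicate 1, at 7.55 and 7.54 in normal replicates 2 and 3, and from 11.80 to 12.17 in the glioma libraries. Mmp14, a membrane-bound metalloproteinase, was at 13.40 in normal replicate 1, 7.74 and 7.14 in normal replicates 2 and 3, and 11.71, 10.70 and 11.35 in glioma. S100a6 was at 13.06 against 8.09 and 7.72, with 11.56, 11.77 and 11.11 in glioma, and Fscn1, which encodes the actin-bundling protein fascin, at 9.03 against at most 4.04, with 11.56, 9.63 and 10.38 in glioma. Kit was at 11.90 against 3.92 and 0.22, with 9.81, 10.77 and 10.09 in glioma. With array weights, limma gave Benjamini-Hochberg adjusted p values of 0.0271 for Kcne3, Apln and Igfbp4, 0.0341 for 5830416P10Rik, 0.0347 for Birc5 and 0.0451 for Cxcl9, with all of them higher in glioma. These weights were 0.122 for normal replicate 1, where Apln and Igfbp4 lay above every glioma library, and 6.84 and 7.60 for normal replicates 2 and 3, so the calls rest mostly on that pair, which is not known to be from separate animals. The smallest adjusted p was 0.875 without weights and 0.142 without normal replicate 1.

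The tip cell genes of normal replicate 1 lay near glioma levels, with 14 of the 19 members above 0 in all libraries higher there than in the other normal libraries. Their median difference lay at percentile 99.83 of 10000 expression-matched random lists, above the -0.78 to 0.80 that held the central 95%. The list was singled out because it stood high in normal replicate 1, so a high percentile was partly set by that choice. The random draw also treats genes as independent, while the estimated correlation within the list was 0.104. The percentile therefore does not decide whether quantile normalization of this library, with few genes detected, is the whole cause. Glioma endothelium under a normal label cannot be told apart from other states, because over genes chosen without this library its median position between the normal mean at 0 and the glioma mean at 1 was 0.90 (bootstrap 95% interval 0.71 to 1.13) for higher genes and 1 (0.98 to 1) for lower genes with its zeros included, and 0.97 and 0.511 (0.385 to 0.614) without them, while glioma libraries treated the same way lay at 0.41 to 0.55 and 0.56 to 1 with zeros and at 0.42 to 0.71 and 0.53 to 0.98 without. A difference shared by the libraries with the earlier date-like numbers in their file names stays open. The tip cell list was -0.94 in glioma replicate 1 relative to glioma replicates 2 and 3, with 6 of 19 members higher there. The exact two-sided binomial p was 0.167, in a test that treats members as independent. These values do not decide on a difference in normal replicate 1. Another state of the endothelium in that sample may also account for the pattern and was not tested.

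Most myeloid markers were highest in glioma replicate 3, with Ctss at 14.15, Spp1 at 12.52, Arg1 at 12.12 and C1qa at 11.69 there. C1qc was at 10.98, C1qb at 10.79 and Fcer1g at 10.68 there, while Ptprc and Adgre1 were listed at 0. Members of the microglia and macrophage list above 0 numbered 22 of 25 in glioma replicate 1, 8 to 14 in the normal libraries and glioma replicate 2, and 21 in glioma replicate 3. The median of the tested members was 5.13 in glioma replicate 1 and 9.47 in glioma replicate 3. Of 24 measured members of the list, 18 (75%, exact 95% interval 53.3% to 90.2%) were highest in that library. Deeper detection of low genes is argued against, since 18 of 125 genes (14.4%, exact 95% interval 8.76% to 21.8%) of the other non-endothelial lists were highest there. Both intervals treat genes as independent, while the estimated correlation within the myeloid list was 0.395, so these intervals are likely too narrow. Myeloid cells or their RNA carried through the sort may account for the pattern. How far the sort for endothelial cells removed such cells was not tested. Without this library the microglia and macrophage list had a camera adjusted p of 0.556, in a range from 0.00109 with other libraries left out.

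The 6 libraries can be split into groups of 3 in 10 ways, which is too few for a share under 0.05. The real split gave 509 genes at an unadjusted p under 0.05 and 0 past the limma adjusted threshold, and 4 of the 10 splits gave as many, with 1124 as the highest other. That split set normal replicates 2 and 3 with glioma replicate 2 against the rest, and the splits with glioma replicate 1 or 3 in its place gave 950 and 1114. These counts, about 2 times the real one, point to a structure of the samples in which normal replicates 2 and 3, whose file names share a date-like number, stand apart from normal replicate 1. For lists past the threshold the real split gave 7 and the highest other 13, with 3 of 10 splits giving as many. For the cell cycle list the real split gave a camera p of 3.11e-10 before adjustment and the next smallest was 9.49e-08, so 1 of 10 splits gave as small a value.

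Sex-linked transcripts differed between libraries whose labels give no sex. Xist was at 13.23 in glioma replicate 1, 5.22 in glioma replicate 3, 3.97 in normal replicate 3 and 0 in the others, and Tsix at 11.30 in glioma replicate 1 and 0 elsewhere. Of the Y-linked genes, Eif2s3y was at 0.41 in glioma replicate 1 and from 7.43 to 7.86 in the others, and Uty at 5.13 in glioma replicate 1 and from 7.17 to 9.76 in the others. Kdm5d was at 1.81 in glioma replicate 1, listed at 0 in normal replicate 1 and from 6.02 to 8.69 in the others, while Ddx3y was at 11.12 in glioma replicate 1 and from 9.76 to 11.34 in the others.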
